A study of Mus musculus with 20 samples.

How the data were processed

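RNA sequencing of TCRTAG CD8 T cells was deposited for 20 libraries in 7 groups. Per the labels' protocols, 5000 live donor cells per activated library were sorted as CD8+ CD90.1+ CFSEhi, and naive cells as CD44-negative. RNA was taken up in Trizol LS and purified with RNeasy Micro columns, cDNA was amplified with SMART-Seq v4 and libraries were made with NEBNext reagents. The kit carries no molecular identifiers and does not mark strand. Per the submitters' processing notes, reads were checked with FastQC, aligned to GRCm38.p6 with STAR 2.7.6a and assigned to genes of GENCODE vM25 with featureCounts 2.0.1, by fragment and gene name, without strand and without multi-mapping reads. The version of FastQC is not given in the sources used here. The deposited values are raw counts per gene and library, not normalised. Group, replicate and time were taken from the labels. No column was without a label.

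Reads of overlapping and antisense genes cannot be told apart in unstranded counts, and close paralogs such as the Ifi200, Ifit, Ly6 and Gbp genes lose reads that map to several of them, so single values of those genes are uncertain. Coordinates come from GENCODE M21 of the same assembly, a release other than the authors' own. For example Oasl1 lies on chromosome 5 at 114923240 to 114937915 and Xcl1 on chromosome 1 at 164931644 to 164935527.

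Total counts were 20026115 to 58966937 per library. A floor of 3 counts corresponds to 0.0509 to 0.150 CPM. Where every library of a group is at 0, an at-least fold sets 3 counts in each library of that group against the mean of the other. Floors cover counting error alone, since reads copied by PCR are counted without molecular identifiers. Fitted log2 values of such genes depend on edgeR's prior count of 0.125 and are no bound.

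Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Of 55291 genes, 16723 passed filterByExpr by group. Libraries were scaled by TMM, and a model with 1 mean per group was fitted to all 20 libraries, so that all groups share the estimate of spread (common biological coefficient of variation 0.794, median prior degrees of freedom 2.19). Contrasts were tested by edgeR's quasi-likelihood F test with robust dispersion, with Benjamini-Hochberg adjustment over all genes, and genes at an adjusted p under 0.05 were called. All adjusted p-values of genes come from this test unless another is named. Contrasts compared tumor with listeria cells at each time, each activated group with naive cells, successive times within each arm, and the tumor and listeria difference at 12 or 24 h with that at 6 h as an interaction.

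Gene lists, 37 in all, of which 11 hold markers of other cell types, were tested in the tumor and listeria comparisons and those with naive cells by limma's camera with a preset correlation of 0.01, beside camera with an estimated correlation and fry. List p-values were adjusted over all lists and contrasts of a family by Benjamini-Hochberg. The lists, the contrasts, the tests and the alternatives were written before the data were examined. So was the rule for naming genes: a panel of 20 genes, the 6 higher and 6 lower genes with the largest changes in each tumor and listeria comparison (4 per direction against naive cells at 6 h and 3 per direction between times and for the interactions), and up to 3 called members of each list per direction. Largest changes were taken among protein-coding genes with a mean of at least 20 CPM in the higher group and, except for the interactions, no overlap between the groups, without markers of other cells, immunoglobulin, T cell receptor, mitochondrial and unnamed genes. 1 gene of the panel is not reported here. Trbv29, Alb, S100a8, S100a9, Xist, the 4 Y genes and the values of single libraries given for Apoe were chosen after their values were seen.

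The alternatives were DESeq2's size factors in edgeR, DESeq2's Wald test, no filter on low counts, a fit of the compared groups alone, removal of marker, mitochondrial and immunoglobulin genes, the replicate number as a block, and leaving out each library in turn. A fit without tumor_24h replicate 1 in comparisons that do not use its group, and a fit of the 16 other activated libraries, were chosen after seeing the data.

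The procedure was tested on simulated data, with 200 changed genes per comparison among 15446. Changed genes were taken at 10 CPM or more in listeria cells and outside the gene lists. Recovery of less expressed genes and of single list members was not estimated. At 1.5-fold, 2-fold and 4-fold changes it recovered 1.5%, 7.5% and 47.0% in the comparison of tumor_6h with listeria_6h, 0%, 16.4% and 65.2% at 12 h, and 0%, 10.4% and 33.3% at 24 h. Of unchanged genes it called 0, 1 and 1. A list shifted by 1 on the log2 scale was found by camera (adjusted p = 1.89e-37), and 0 of 110 tests of unshifted lists were called. The simulated spread was that estimated from all 20 libraries, tumor_24h replicate 1 included, so recovery is not that of the compared groups alone. Simulated genes were drawn independently of each other, so this does not test the preset correlation. List calls under other groupings of the real libraries are given in the closing section. No gene that failed the filter was tested, no sample was left out of the main comparisons, and splicing and antisense transcription were not analysed here.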

Results

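RNA was measured in CD8 T cells of mice whose T cells carry TCRTAG, a transgenic T cell receptor that recognises a peptide of the SV40 large T antigen (TAG). Cells transferred into other mice were recovered 6, 12 and 24 h later, either from liver tumors or from the spleens of mice infected with Listeria that carry TAG. Recovered cells were sorted as live donor cells that had kept CFSE, a dye that cell division dilutes. Naive TCRTAG cells from spleen, sorted as CD44-negative, were the reference. The 20 libraries fall into 7 groups: naive, listeria_6h, listeria_12h, listeria_24h, tumor_6h and tumor_12h with 3 libraries each, and tumor_24h with 2. The labels do not say that the replicates came from separate animals, so each p-value measures the spread between these samples, which may be technical. Liver and spleen differ with the arm, so an effect of the tissue and one of the tumor are not separated in any tumor and listeria comparison.

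Total counts were 20026115 to 40252987 per library in the 17 libraries of activated cells and 41786399 to 58966937 in the 3 naive libraries. The transgenic receptor marked the cells in each library: Trbv29 took 95.66% to 99.38% of the counts of all Trbv genes. Genes with at least 1 count numbered 14583 to 18931 in 19 libraries. The remaining library, tumor_24h replicate 1, had 10214 at a total of 36218003, and its expression values correlated with those of the nearest other library at 0.825 across genes, which are not independent replicates. It stayed in every main comparison, and the values without it are given where they move a count. Of 55291 genes in the files, 16723 were tested. Levels are TMM-normalised CPM (counts scaled to a library of 1e6) as mean ± SD, with n = 3 unless stated.

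**Figure D1:**
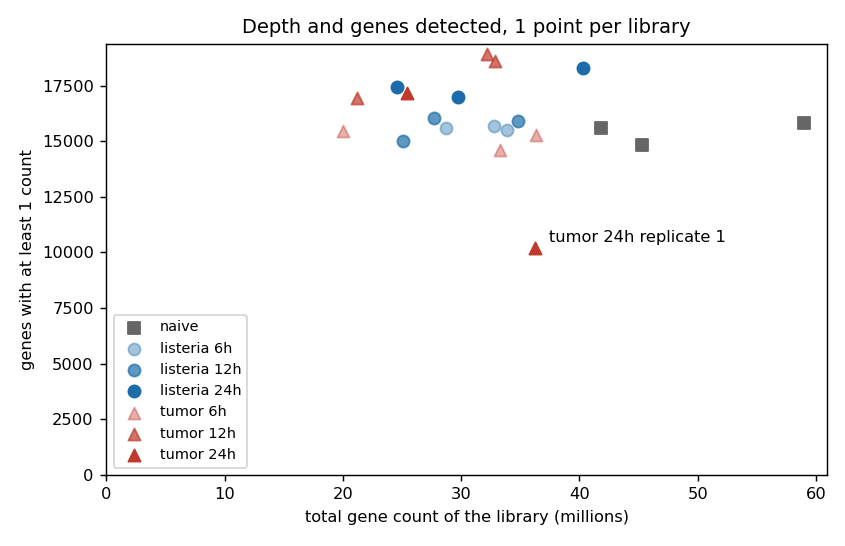
Total gene count per library in units of 1e6 (horizontal axis) against the number of genes with at least 1 count (vertical axis), with 1 point per library, colour and shape for the group and darker shades for later times. Tumor_24h replicate 1 lies at 10214 genes and the other 19 libraries between 14583 and 18931.

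The first comparison asks how the same T cells, 6 h after transfer, differ when antigen is met in a liver tumor or during an acute infection. Tumor cells at 6 h carried far more mRNA of Xcl1 and Ccl3, chemokines that attract dendritic cells and inflammatory leukocytes, and of Spry1, an inhibitor of receptor tyrosine kinase and TCR signalling. Xcl1 was at 6739 ± 1058 CPM in tumor and 507 ± 128 in listeria cells, Ccl3 at 4716 ± 722 and 606 ± 228, and Spry1 at 1476 ± 146 and 209 ± 52.2. Genes of the interferon response went the other way: Oasl1, an interferon-induced regulator of antiviral signalling, had no count in any tumor_6h library and 244.0 ± 23.3 CPM in listeria_6h. So did the effector genes Gzmb, the cytotoxic protease granzyme B, at 366 ± 95.4 CPM in tumor and 8477 ± 1320 in listeria cells, and Batf, an AP-1 transcription factor of effector differentiation, at 24.6 ± 3.03 and 559 ± 20.6. Tcf7, which encodes TCF1, a transcription factor of naive and memory T cells, was also lower in tumor cells, at 69.0 ± 7.37 CPM against 255 ± 89.6.

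Several early activation genes did not pass between the arms at 6 h. Since 7.5% of simulated 2-fold changes were recovered there, equal levels are not shown. Nr4a1, an orphan nuclear receptor induced by TCR signalling, was at 2650 ± 12.3 CPM in tumor and 2226 ± 543 in listeria cells (adjusted p = 0.903 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Tnf stood at 1029 ± 29.9 and 1003 ± 108 (adjusted p = 1.00), Myc at 4086 ± 507 and 2912 ± 810 (0.412) and Irf4 at 639 ± 19.5 and 722 ± 80.7 (1.00). Il2 stood at 310 ± 13.9 and 135 ± 49.9 CPM (log2 1.20, adjusted p = 0.0986; 0.0113 to 0.305 over 14 alternatives, past the threshold in 4). Il2ra was at 343 ± 74.3 and 685 ± 108 (log2 -1, adjusted p = 0.218; 0.00221 to 0.430, past it in 2). Of 25 genes of the early TCR response list, 2 were higher in tumor (Spry1 and Egr2), 4 were lower, among them Batf and Ier3, and 19 did not pass; adjusted over the list alone, 3 were higher and 7 lower. Immediate early genes raised by tissue handling had 4 of 18 lower, including Socs3 and Btg2, and none higher (7 and 3 adjusted over the list alone; median -0.92, or -0.57 without listeria_6h replicate 1; adjusted p = 0.000525, and 0.139 with an estimated correlation). Egr2, a transcription factor of TCR signalling and anergy, was at 459 ± 37.4 CPM in tumor and 238 ± 46.4 in listeria cells (log2 fold change 0.95, adjusted p = 0.0405). This call was lost on leaving out listeria_6h replicate 2 or 3 or any 1 tumor_6h library, and without the filter on low counts (0.0563), with adjusted p from 0.0039 to 0.182 over 14 alternatives.

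In all, 109 genes were higher and 471 lower in tumor_6h than in listeria_6h. Xcl1 had a log2 fold change of 3.73 (adjusted p = 0.000454), Ccl3 of 2.96 (4.86e-06) and Spry1 of 2.82 (0.000311). Itm2a, a membrane protein induced on T cell activation, reached 527 ± 92.9 CPM in tumor and 43.5 ± 2.78 in listeria cells (log2 3.60, adjusted p = 4.2e-08). Dusp4, a phosphatase of MAP kinases, had a log2 fold change of 3.58 (0.00202) and Atp2a3, a calcium pump of the endoplasmic reticulum, of 3.15 (0.0026). Each of these 6 passed in all 14 alternatives. Slco4a1, an organic anion transporter, was higher by 4.29 on the log2 scale (0.0112) and Fhl2, a LIM domain protein, by 3.03 (0.0470). Slco4a1 was lost without listeria_6h replicate 2 or 3 (adjusted p up to 0.068 over 14 alternatives), and Fhl2 without listeria_6h replicate 1 or 3 or any 1 tumor_6h library (up to 0.182).

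The type I interferon response list was the most uniform difference. Of its 36 members, 34 were lower in tumor_6h, none was higher and 2 did not pass; adjusted over the list alone, all 36 were lower. The median log2 fold change was -7.28, and -6.86 with genes at 0 set to their bound, and the list passed limma's camera test against all other genes (adjusted p = 1.7e-133, and 1.59e-06 with an estimated correlation). Oasl1 was at least 2198-fold lower in tumor cells, Ifit3b at least 802.2-fold, Ifit1bl1 at least 648.5-fold, Mx1 at least 519.9-fold and Ifi206 at least 261.2-fold, each at 0 in all 3 tumor libraries and passing in all 14 alternatives. Ccrl2, a chemokine-binding receptor outside the list, was at least 425.4-fold lower. Of the 28 genes of interferon gamma response and antigen presentation, 24 were lower and none higher (26 and none adjusted over the list alone), with a median of -4.10 (adjusted p = 5.12e-90, and 2.67e-07 with an estimated correlation). Gbp2, an interferon-induced GTPase, was at 1.17 ± 1.03 CPM in tumor and 524 ± 47.9 in listeria cells. Summed over the type I list, tumor_6h libraries held 174 to 204 CPM, listeria_6h libraries 9163 to 10002.5 CPM and naive libraries 3248 to 3519 CPM.

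Cytotoxic granule genes were lower in tumor_6h as a list: 6 of 15 were lower and none higher (7 and none adjusted over the list alone), with a median of -0.94, or -0.62 without tumor_6h replicate 3 (adjusted p = 1.18e-08, and 0.00615 with an estimated correlation). Among them Ctsw, which encodes cathepsin W, was at 19.3 ± 4.35 CPM against 117 ± 6.78. Gzmb had a log2 fold change of -4.53 (adjusted p = 0.0147), a call lost on leaving out any 1 tumor_6h library (3.52e-08 to 0.0764 over 14 alternatives). Tbx21, which encodes the effector transcription factor T-bet, was lower by -2.48 on the log2 scale (0.00604, 14 of 14 alternatives). Ifng was at 232 ± 29.9 CPM in tumor and 612 ± 161 in listeria cells (log2 -1.40, adjusted p = 0.0345), and this call was lost without listeria_6h replicate 2 or 3 or any 1 tumor_6h library (0.0011 to 0.138). Inflammatory cytokine receptors and signalling had 5 of 25 members lower and none higher (11 and none adjusted over the list alone; median -0.96, adjusted p = 6.01e-08, and 0.0109 with an estimated correlation). Stat3, at 326 ± 63.2 against 1099 ± 274 CPM, and Il15ra, at 28.7 ± 5.23 against 87.5 ± 13.5 CPM, were 2 of these.

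The effector cytokine and chemokine list split. Of 20 members, 4 were higher in tumor_6h, among them Xcl1, Ccl3 and Lta, and 3 were lower, among them Il21 at 0 in each tumor library; adjusted over the list alone, 8 were higher and 4 lower. Its median was 1.22 (adjusted p = 0.000498, and 0.115 with an estimated correlation). Inhibitory receptors also went both ways. Cd160 was higher in tumor at 498 ± 8.93 against 144 ± 35.9 CPM (log2 1.79, adjusted p = 0.000311), while Ctla4 was lower at 1.26 ± 1.14 against 195 ± 43.4 CPM (log2 -7.29, 0.0116). Ctla4 was lost without tumor_6h replicate 1 (adjusted p up to 0.0639 over 14 alternatives). The list of 17 had 1 member higher and 3 lower (4 and 4 adjusted over the list alone), a median of -0.06, a mean of -1.40 and an upward camera test (adjusted p = 0.597), so these differ in sign. The sign of the median was not stable either, from -0.39 without tumor_6h replicate 1 to 0.61 without listeria_6h replicate 3. Pdcd1, which encodes the inhibitory receptor PD-1, was at 760.6 ± 30.5 CPM in tumor and 304.0 ± 41.9 in listeria cells, with no overlap between the groups, as chance gives for 10% of genes at 3 against 3. It did not pass in the fit of all 20 libraries (log2 1.32, adjusted p = 0.341). It passed in 2 of 14 alternatives, the fit of these groups alone (0.00335) and that of 16 activated libraries, with adjusted p from 3e-06 to 0.581. Both leave out the naive libraries and tumor_24h replicate 1, which enter the shared estimate of spread in the main fit. The failure to pass there thus rests in part on libraries that are not compared here. Lag3, Havcr2 and Entpd1 were under 10 CPM in both groups and Tox, a transcription factor of T cell dysfunction, was at 21.4 ± 8.63 and 8.81 ± 2.81 CPM, and none of these passed.

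Negative regulators of TCR signalling had 6 of 29 higher, among them Rgs2 and Dusp4, and 4 lower, among them Socs1 and Dgka (10 and 7 adjusted over the list alone; adjusted p = 0.105). Naive and memory genes had 4 of 25 higher, including Bach2, and 8 lower, including Tcf7 and Ly6c2 (4 and 9 adjusted over the list alone; median -1.51, adjusted p = 7.17e-08, and 0.139 with an estimated correlation). Bach2 was lost without listeria_6h replicate 2 or 3 or tumor_6h replicate 1 or 2 (adjusted p up to 0.0905 over 14 alternatives). Tcf7 had a log2 fold change of -1.89 (8.37e-05). The CD8 coreceptor genes were lower in tumor cells: Cd8a at 340 ± 37.7 against 1351 ± 104 CPM (log2 -1.99, adjusted p = 1.03e-05) and Cd8b1 at 370.1 ± 14.1 against 1178 ± 67.5 (-1.67, 8.73e-06). They belong to a CD8 identity list with 5 of 16 lower and none higher (5 lower and 2 higher adjusted over the list alone; adjusted p = 0.000644, and 0.158 with an estimated correlation). Homing and chemokine receptor genes had 2 higher and 6 lower of 20 (3 and 6 adjusted over the list alone; adjusted p = 1.79e-06, and 0.128 with an estimated correlation).

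Markers of other cell types moved with the arm. Beside the interferon lists, 5 of 15 dendritic cell genes were lower in tumor_6h (9 adjusted over the list alone; median -3.62, or -3.19 at the bounds; adjusted p = 7.14e-13, and 0.0116 with an estimated correlation), 2 of them Bst2 and Ccr7, which T cells also express. B cell and plasma cell genes had 4 of 17 lower (8 adjusted over the list alone; median -3.62; adjusted p = 8.87e-08, and 0.0326 with an estimated correlation), with Cd79b at 2.76 ± 1.35 against 29.8 ± 8.44 CPM. Of 19 macrophage genes 3 were lower (5 adjusted over the list alone; adjusted p = 2.05e-06, and 0.124 with an estimated correlation), and Marco was at 0 in tumor and 16 ± 10.8 CPM in listeria cells. Hepatocyte genes had 1 of 32 lower and none higher (adjusted p = 0.295).

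Leaving out single libraries moved the number of genes higher in tumor_6h from 109 to 71 without listeria_6h replicate 2, 61 without listeria_6h replicate 3, 72 without tumor_6h replicate 1 and 70 without tumor_6h replicate 2. Without tumor_24h replicate 1, an alternative chosen after seeing the data, 316 were higher and 818 lower, and DESeq2's Wald test gave 419 and 938.

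The comparison at 12 h asks the same question later in the response. Interferon-induced genes were still far lower in tumor cells: Ly6a, a surface protein of activated T cells, was at 18.0 ± 4.93 CPM in tumor and 3268 ± 386 in listeria cells, and Isg15, a ubiquitin-like modifier, at 4.55 ± 2.08 and 742 ± 91.6. The chemokine genes Xcl1, at 4974 ± 843 against 327 ± 49.7 CPM, and Ccl3, at 3062 ± 343 against 401 ± 18.0, were still higher in tumor cells. The effector genes Gzmb, at 87.4 ± 13.5 against 6644 ± 1254 CPM, and Tbx21, at 50.5 ± 26.1 against 846 ± 278, were lower. Cd5, a surface receptor that dampens TCR signalling, was higher in tumor at 664 ± 200 against 176 ± 45.7 CPM.

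At 12 h 87 genes were higher and 199 lower in tumor cells. The largest higher changes by the naming rule were in Ccl9, a chemokine (log2 5.20, adjusted p = 0.000491), Slco4a1 (4.87, 0.00841), Slc9b2, a sodium and proton exchanger (4.68, 0.03), Ubash3b, a phosphatase that limits TCR signalling (4.63, 0.00939), Xcl1 (3.93, 0.000491) and Fhl2 (3.89, 0.0197). Slc9b2 was lost on leaving out any 1 of the 6 libraries (adjusted p up to 0.183 over 14 alternatives), Slco4a1 and Ubash3b without listeria_12h replicate 1 or 2 (up to 0.0657 and 0.0702), and Fhl2 without any 1 listeria_12h library or tumor_12h replicate 1 or 3 (up to 0.117). The largest lower changes by the same rule were in Cxcl10 (-9.52, 0.00427), Ly6c1 (-7.80, 0.00131), Ly6a (-7.51, 9.02e-09), Isg15 (-7.34, 1.84e-07), Usp18 (-7.23, 0.000134) and Ifit3 (-6.36, 0.00331), which passed in all 14 alternatives and are interferon-induced genes or, for Ly6c1, a surface antigen of the Ly6 family.

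Of the type I interferon list 20 of 36 were lower in tumor_12h and none higher (34 and none adjusted over the list alone; median -4.92, adjusted p = 2.44e-119, and 5.28e-07 with an estimated correlation). Of the interferon gamma list 15 of 28 were lower and none higher (26 and none adjusted over the list alone; median -2.95, adjusted p = 1.92e-77, and 4.14e-07 with an estimated correlation). The early TCR response list was lower at 12 h, with 8 of 25 lower and 1 higher (11 and 3 adjusted over the list alone; median -0.28, or -0.06 without listeria_12h replicate 3 and -0.43 without replicate 2; adjusted p = 5.54e-09, and 0.00727 with an estimated correlation). Batf was at 35.1 ± 8.73 against 321 ± 57.9 CPM (log2 -3.19, 2.62e-07), while Spry1 stood higher at 723 ± 161 against 101 ± 48.6 CPM (2.84, 0.000485). Genes raised by tissue handling had 4 of 18 lower and none higher (7 and 1 adjusted over the list alone; adjusted p = 7e-08, and 0.0213 with an estimated correlation). Effector transcription factors, with 2 of 13 lower, Tbx21 and Id2, had a median of -0.92 (adjusted p = 1.14e-05, and 0.0171 with an estimated correlation; 2 adjusted over the list alone).

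Cytotoxic granule genes had 4 of 15 lower and 1 higher (6 and 1 adjusted over the list alone; median -0.72, adjusted p = 2e-07, and 0.0102 with an estimated correlation). The higher member was Prf1, the pore-forming protein perforin, at 455 ± 73.4 against 174.0 ± 26.3 CPM (log2 1.39, 0.000485), and the lower ones included Gzmb (log2 -6.25, 0.00346) and Nkg7 (-1.39, 0.000225). Ifng was at 124 ± 24.2 against 666 ± 158 CPM (-2.42, 0.00123), Tnf at 322 ± 42.5 against 612 ± 85.8 (-0.92, 0.00151) and Cd69, an early activation marker, at 105 ± 4.92 against 608 ± 136 (-2.53, 0.00209), each lower in tumor in all 14 alternatives. Il2ra, the high-affinity interleukin 2 receptor chain, was at 150.0 ± 11 against 520.1 ± 83.2 CPM (-1.79, 0.0224), a call lost without listeria_12h replicate 1 or 2 or any 1 tumor_12h library (2.13e-05 to 0.12).

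Inhibitory receptors had 3 of 17 higher, Cd5, Cd160 and Cd96, and none lower (5 and 1 adjusted over the list alone; median 1.28, or 0.50 without tumor_12h replicate 2; adjusted p = 0.000407, and 0.093 with an estimated correlation). Cd96 was lost without listeria_12h replicate 2 or 3 or tumor_12h replicate 1 or 3 (adjusted p from 0.00015 to 0.138 over 14 alternatives). Pdcd1 was at 756 ± 38.5 CPM in tumor and 160.5 ± 2.65 in listeria cells (log2 2.24, adjusted p = 0.107) and passed in 4 of 14 alternatives, the Wald test, the fit of these groups alone, that of 16 activated libraries and that without tumor_24h replicate 1 (7.13e-08 to 0.365). Negative regulators had 6 of 29 higher, including Rgs2, and 4 lower, including Socs1 and Socs3 (11 and 5 adjusted over the list alone; adjusted p = 0.0306, and 0.163 with an estimated correlation). Of the naive and memory list 4 of 25 were higher, including Bach2, at 108 ± 19 against 25.7 ± 10.8 CPM, and Id3, at 549 ± 41.9 against 213 ± 1.82, and 4 were lower, including Satb1, at 59.6 ± 12.5 against 388 ± 78.5 (6 and 7 adjusted over the list alone; adjusted p = 0.0522). Effector cytokines and chemokines had 4 of 20 higher and 3 lower (7 and 5 adjusted over the list alone; median 1.11, adjusted p = 0.0259, and 0.289 with an estimated correlation). The list of negative regulators was lost without listeria_12h replicate 1 (0.169) or 2 or tumor_24h replicate 1, and that of cytokines without listeria_12h replicate 1 or 3 (0.356) or tumor_24h replicate 1.

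Cell cycle lists were higher in tumor cells at 12 h, where neither had passed at 6 h (adjusted p = 0.940 for S phase and 0.602 for mitosis). DNA replication and S phase had 1 of 30 higher, Mcm7, and none lower (2 and none adjusted over the list alone; median 0.69, adjusted p = 1.68e-05, and 0.163 with an estimated correlation). Mcm7 was lost without any 1 of the 6 libraries (adjusted p up to 0.185). Mitosis had 1 of 25 higher, Cenpa (log2 3.25, 0.00331), and none lower (1 and none adjusted over the list alone; median 1.26, or 0.80 without tumor_12h replicate 2; adjusted p = 0.000498, and 0.152 with an estimated correlation).

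Among the markers of other cell types, neutrophil and monocyte genes and, to a lesser extent, macrophage genes stood apart in 1 library of tumor_12h. Summed over the macrophage list, tumor_12h replicate 2 held 3.74 times the mean of replicates 1 and 3. Summed over the neutrophil and monocyte list it held 2919 CPM, with S100a8 at 333 and S100a9 at 538 CPM, and replicates 1 and 3 held 28.8 and 175 CPM. The list had 1 of 15 lower and none higher (8 higher and 1 lower adjusted over the list alone; median 9.4, or 6.25 at the bounds; adjusted p = 0.0294, and 0.596 with an estimated correlation) and was lost without tumor_12h replicate 2 (median 5.96) or listeria_12h replicate 1. Of 32 hepatocyte genes none passed, also adjusted over the list alone (median 3.01, or 1.13 at the bounds; adjusted p = 0.00124, and 0.152 with an estimated correlation). The median was 1.24 without tumor_12h replicate 2 and 4.90 without listeria_12h replicate 3. Dendritic cell genes had 2 of 15 lower, Bst2 and Ccr7, and none higher (2 and none adjusted over the list alone; median -0.76, adjusted p = 4.04e-06, and 0.093 with an estimated correlation). That median was -1.67 without tumor_12h replicate 2, -0.33 without tumor_12h replicate 3 and -0.48 without listeria_12h replicate 2 or 3. Of 17 B cell and plasma cell genes 1 was higher, Ighm, and none lower (1 and none adjusted over the list alone). The list as a whole went down (median -1.28, adjusted p = 0.0452, and 0.349 with an estimated correlation). It was lost without listeria_12h replicate 3 or tumor_12h replicate 1 (0.251) or 3 (0.140). Its median was -2.68 without tumor_12h replicate 2.

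Single libraries moved the 87 genes higher in tumor_12h to 54 without listeria_12h replicate 1, 48 without listeria_12h replicate 2 and 51 without tumor_12h replicate 1, and the 199 lower to 129 without tumor_12h replicate 1. Without tumor_24h replicate 1, an alternative chosen after seeing the data, the counts were 232 and 383, and DESeq2's Wald test gave 316 and 420.

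**Figure D2:**
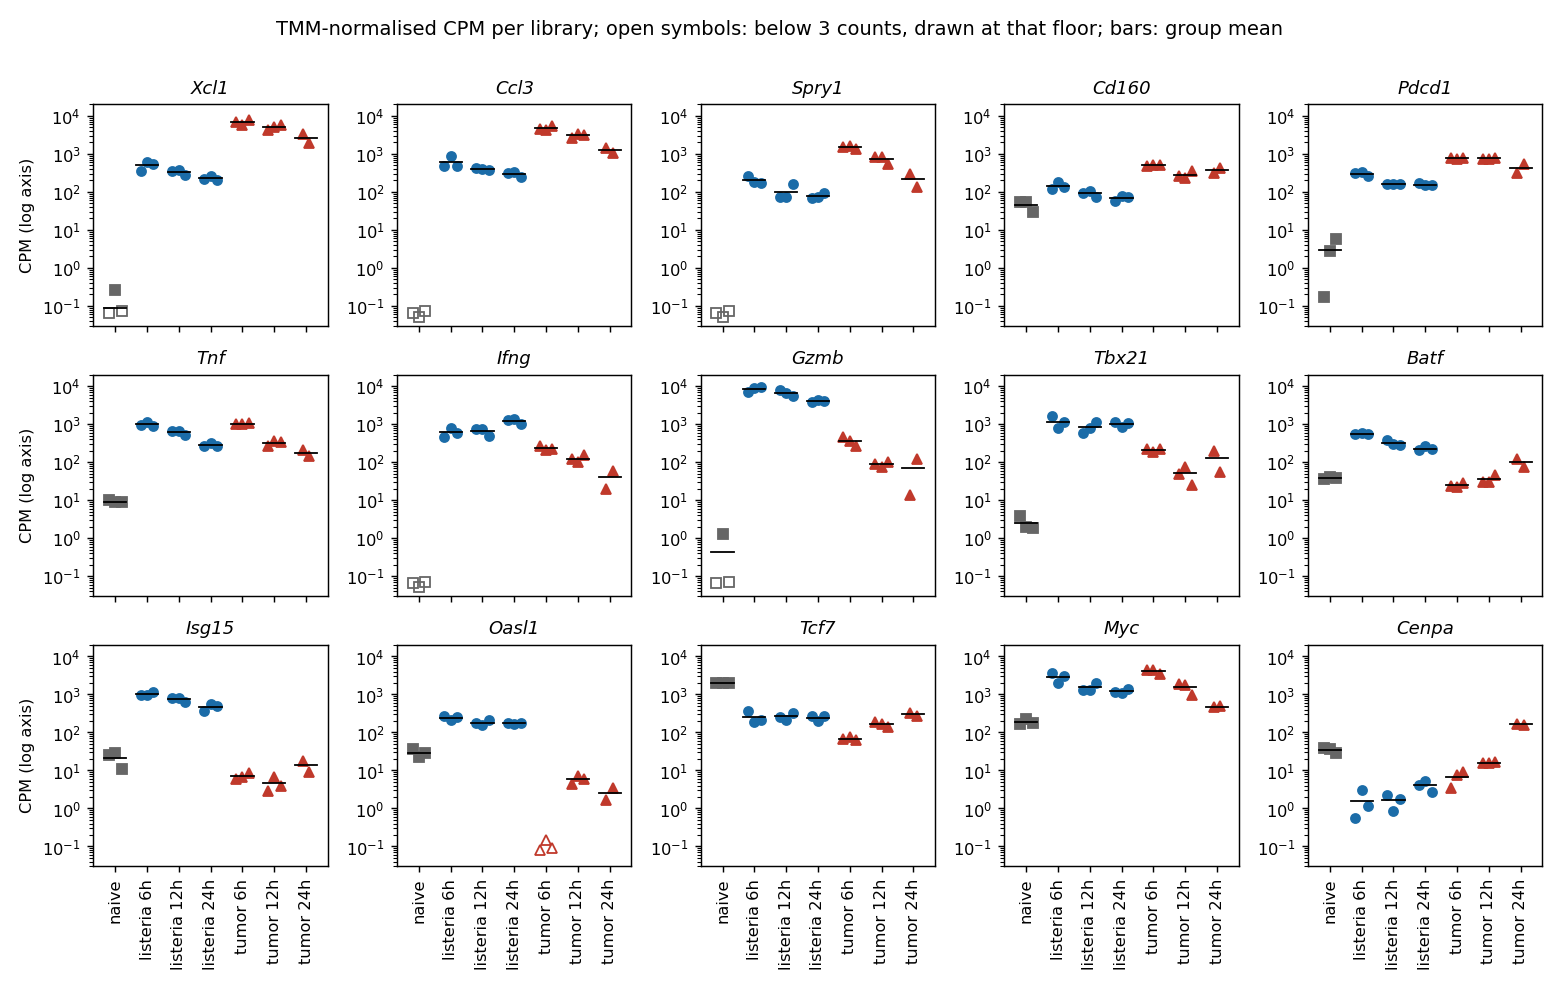
TMM-normalised CPM on a log axis for 15 genes, with 1 symbol per library, a bar for the group mean and open symbols, drawn at the level of 3 counts, for libraries under that level. Xcl1, Ccl3 and Cd160 lay higher in tumor (triangles) than in listeria cells (circles) at each time, and Gzmb, Tbx21, Isg15 and Oasl1 lay lower.

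At 24 h, with 2 tumor and 3 listeria libraries, the comparison asks whether the difference persists to the end of the first day. Ifng, the effector cytokine interferon gamma, was at 39.8 ± 28.0 CPM in tumor (n = 2) and 1228 ± 174 in listeria cells (n = 3), and Gzmb at 68.5 ± 77.4 and 4024 ± 304. Interferon-induced genes were again lower in tumor cells, as for Ly6a at 27.6 ± 9.87 and 2496 ± 240.4 CPM, and Oasl1 at 2.56 ± 1.19 and 172 ± 4.49. Higher in tumor cells were Cenpa, the centromeric histone variant needed for mitosis, at 165.0 ± 4.48 and 4.13 ± 1.33 CPM, and Cd160, at 369.8 ± 78.6 and 70.6 ± 10.4.

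Here 290 genes were higher and 337 lower in tumor cells. The largest higher changes by the naming rule were in the chemokine genes Ccl1 (log2 8.36, adjusted p = 0.0298) and Ccl9 (6.80, 0.000158), in Bdh2 (8.24, 0.0476), Pglyrp1, an antimicrobial peptidoglycan-binding protein (7.65, 0.0234), Nrgn (6.70, 0.0303) and Hsd11b1, an enzyme that regenerates active glucocorticoid (5.37, 5.04e-05). Ccl9 and Hsd11b1 passed in 11 of 12 alternatives, and the other 4 in 6 to 8 of 12. Ccl1 was lost without listeria_24h replicate 1 or 3 or tumor_24h replicate 1, Bdh2 without any 1 listeria_24h library or without the filter on low counts, Pglyrp1 without any 1 listeria_24h library or tumor_24h replicate 1 and Nrgn without any 1 listeria_24h library. In the fit of these 5 libraries alone the 4 had adjusted p of 0.278, 0.215, 0.163 and 0.145. Without listeria_24h replicate 2 the log2 of Ccl1 was 14.02. Neutrophil and monocyte markers summed to 4713 and 1037 CPM in tumor_24h replicates 1 and 2 and to 259.2, 456.2 and 375.7 CPM in the listeria_24h libraries. RNA from these cells is therefore not excluded for Pglyrp1. Some called genes that the naming rule leaves out had larger fitted drops, as Il21 (-10.61, 0.00363). The largest lower changes by that rule, ranked on all 5 libraries, were in Cxcl10 (-8.60, 0.0215), Ly6a (-6.50, 5.81e-07), the cytokine gene Lif (-6.23, 0.0146), Oasl1 (-6.08, 2.72e-06), Ifit3 (-6.01, 0.0164) and Gzmb (-5.88, 0.0159). All but Cxcl10, which was lost without listeria_24h replicate 3, passed in 11 of 12 alternatives. Without tumor_24h replicate 2 the log2 of Lif was -16.10, that of Cxcl10 -14.99 and that of Ifit3 -13.72, which would change the ranking.

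Of the type I interferon list 14 of 36 were lower and none higher (24 and none adjusted over the list alone; median -3.25, or -8.96 without tumor_24h replicate 2; adjusted p = 9.37e-24, and 0.00700 with an estimated correlation), and of the interferon gamma list 8 of 28 were lower and none higher (11 and none adjusted over the list alone; median -1.40, adjusted p = 4.46e-10, and 0.00767 with an estimated correlation). Cell cycle lists were again higher in tumor cells. DNA replication and S phase had 3 of 30 higher and none lower (7 and none adjusted over the list alone; median 0.83, or 0.06 without tumor_24h replicate 2 and 1.27 without replicate 1; adjusted p = 6.82e-07, and 0.139 with an estimated correlation). The S phase list was lost without tumor_24h replicate 2, and of its genes Mcm7 was lost without listeria_24h replicate 2 or 3 or tumor_24h replicate 2 and in the fit of these 5 libraries alone (adjusted p = 0.195). Mitosis had 2 of 25 higher, Cenpa (log2 5.32, 0.000142) and Cdc20 (1.81, 0.00409), and none lower (4 and none adjusted over the list alone; median 2.10, or 0.21 without tumor_24h replicate 2; adjusted p = 2.1e-07, and 0.0726 with an estimated correlation). Ribosome biogenesis had 3 of 30 lower, including Rrs1, and none higher (6 and none adjusted over the list alone; median -0.65, or -1.08 without tumor_24h replicate 2; adjusted p = 3.79e-05, and 0.0877 with an estimated correlation).

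Inhibitory receptors had 4 of 17 higher, including Cd160 (log2 2.39, adjusted p = 9.5e-05), Cd96 (1.90, 0.00169) and Cd5 (1.77, 0.00114), and none lower (4 and 1 adjusted over the list alone). The median of that list was -0.55 (0.42 without tumor_24h replicate 1 and -2 without replicate 2), the mean -0.57 and the camera test upward (adjusted p = 0.0153, and 0.187 with an estimated correlation; 0.286 without tumor_24h replicate 2). Pdcd1 was at 433 ± 164 and 156 ± 9.62 CPM (log2 1.48, adjusted p = 0.279; 1.08e-05 to 0.472 over 12 alternatives). Ctla4 was at 6.75 ± 9.55 and 56.4 ± 8.75 CPM (0.317). Naive and memory genes had 6 of 25 higher, including Dapl1 and Slamf6, and 2 lower (8 and 2 adjusted over the list alone; median 0.29, or 0.17 and 0.15 without listeria_24h replicate 1 and 2, 0.54 without tumor_24h replicate 1 and -1.27 without replicate 2; adjusted p = 0.0306, and 0.554 with an estimated correlation), and the list was lost without listeria_24h replicate 1 or tumor_24h replicate 2 (0.939). Tcf7 stood at 301 ± 37.5 and 246 ± 42.7 CPM (0.594). The CD8 identity list had 6 of 16 higher, including Cd3g and Trbc1, and 3 lower (7 and 4 adjusted over the list alone; adjusted p = 0.00200, and 0.176 with an estimated correlation) and was lost without tumor_24h replicate 2.

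Early TCR response genes had 9 of 25 lower, including Nfkbia and Dusp5, and 2 higher (10 and 2 adjusted over the list alone; adjusted p = 0.0121, and 0.160 with an estimated correlation; 0.621 without tumor_24h replicate 2). Cytotoxic granule genes had 2 of 15 higher, Ctsw at 233 ± 77.2 and 40.7 ± 3.13 CPM and Prf1 at 315 ± 34.0 and 141.0 ± 10.6 CPM, and 3 lower, including Gzmb and Serpinb9 (2 and 5 adjusted over the list alone; adjusted p = 0.792). Effector cytokines and chemokines had 5 of 20 higher, including Xcl1 at 2645 ± 1074 and 229 ± 29.4 CPM, and 5 lower, including Ifng (log2 -4.95, 5.34e-05; 7 and 6 adjusted over the list alone; list adjusted p = 0.0289, and 0.289 with an estimated correlation), and the list was lost without any 1 of listeria_24h replicate 1 or 3 or tumor_24h replicate 1 or 2. Il2ra (log2 -2.76, 0.00327) and Tbx21 (-3.01, 0.00735) were lower in 11 of 12 alternatives. Myc was lower at 479 ± 9.68 and 1219 ± 160.4 CPM (-1.35, 0.0196), a call lost without listeria_24h replicate 3 or tumor_24h replicate 1 and in the fit of these 5 libraries alone (0.145).

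Other cell types' markers moved with tumor_24h too. Hepatocyte genes had 2 of 32 higher and none lower (2 and none adjusted over the list alone; median 3.00, or 0.99 at the bounds, and 0.45 and 0 without tumor_24h replicate 1 and 2; adjusted p = 0.000498, and 0.093 with an estimated correlation). Apoe, 1 of these, was at 955 CPM in tumor_24h replicate 1 and 50.3 in replicate 2 and was lost without any 1 listeria_24h library or tumor_24h replicate 1 (adjusted p up to 0.513 over 11 alternatives), and Alb, the most abundant hepatocyte transcript, was at 0 and 2.08 CPM. The macrophage list summed to 1730 and 614.7 CPM in replicates 1 and 2. The other higher gene was Dbi (log2 0.996, adjusted p = 0.0467), which passed in 3 of 11 alternatives. Of the 32 hepatocyte genes, 2 were at 10 CPM or more in every naive library, so T cells may express some of them. Neutrophil and monocyte genes had none of 15 past the test (2 higher adjusted over the list alone; median 7.32, or 3.84 without tumor_24h replicate 1; adjusted p = 1.14e-05, and 0.223 with an estimated correlation), with sums of 4713 and 1037 CPM in replicates 1 and 2. Of 15 dendritic cell genes 1 was higher and 3 lower (1 and 3 adjusted over the list alone; median -1.84, or -2.88 without tumor_24h replicate 1; adjusted p = 0.00614, and 0.285 with an estimated correlation; 0.899 without tumor_24h replicate 2).

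The counts at 24 h rested on the pair of tumor libraries. They were 350 higher and 295 lower without tumor_24h replicate 1, of which 169 and 167 were among the main calls, and 899 and 4880 without replicate 2; without listeria_24h replicate 1 they were 142 and 185, without replicate 2 157 and 191, and without replicate 3 148 and 170. In edgeR's fit of these 5 libraries alone 0 genes passed, with 1711 at an unadjusted p under 0.05, against 785 and 944 by DESeq2's Wald test and 417 and 352 in the fit of 16 activated libraries, which was chosen after seeing the data.

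Calls recurred between times. Of the genes called, 45 were higher and 162 lower in tumor at both 6 and 12 h, where independent lists of these sizes would share 0.6 and 5.6. At all 3 times 21 genes were higher and 66 lower. At 6 and 24 h, 30 were higher and 82 lower at both times (1.9 and 9.5 for independent lists), while 52 genes lower in tumor at 6 h were higher at 24 h. The 3 comparisons share 1 filter and 1 estimate of spread, so the values for independent lists are not a chance level.

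**Figure D3:**
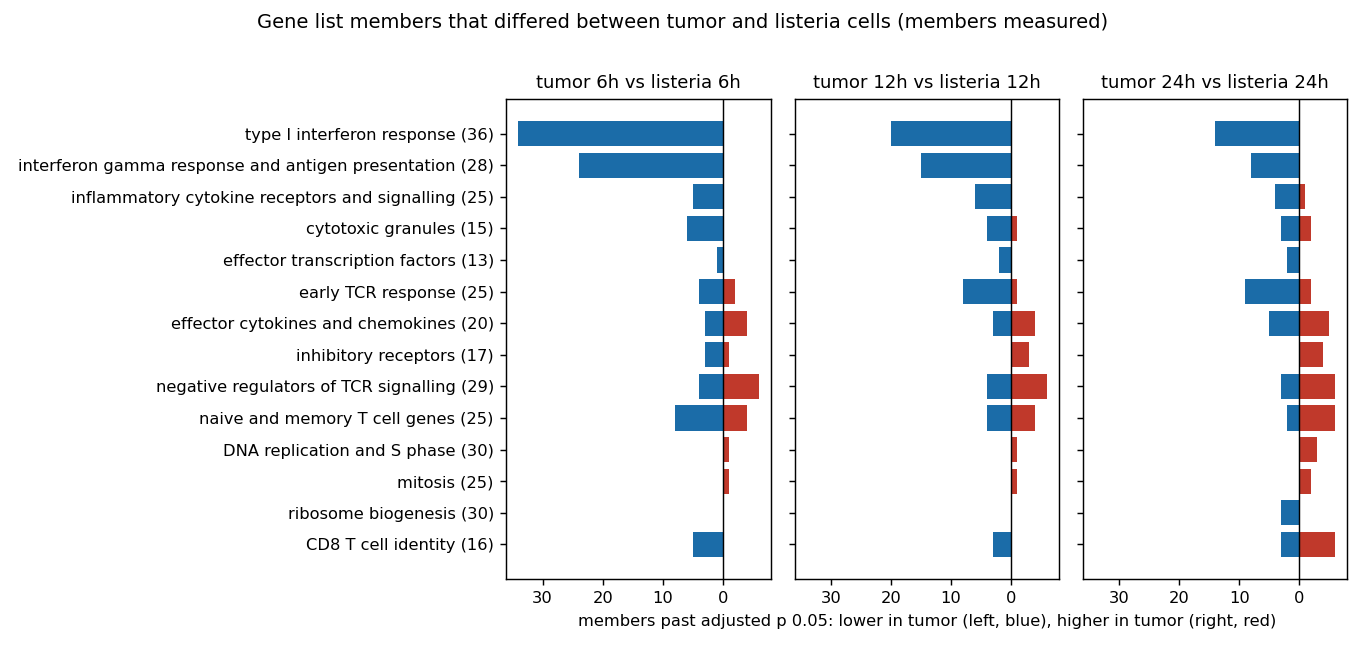
Number of members of 14 gene lists that were lower (left, blue) or higher (right, red) in tumor than in listeria cells at 6, 12 and 24 h, with the members measured in parentheses. Of 36 type I interferon genes 34, 20 and 14 were lower at the 3 times and none was higher.

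Whether the tumor and listeria difference itself changed with time was tested by an interaction term. Between 6 and 12 h the difference changed for 47 genes, of which 43 moved upward in tumor relative to listeria cells and 4 downward. Oasl1 rose from 0 to 5.82 ± 1.41 CPM in tumor cells, at least 52.4-fold, while listeria cells went from 244.0 ± 23.3 to 182 ± 29.4 (interaction log2 11.05, adjusted p = 3.23e-06, a fitted value that depends on the prior count because tumor_6h is at 0). Psmb9, an immunoproteasome subunit, went from 13.5 ± 2.67 to 45.6 ± 9.25 CPM in tumor cells and stood at 244.1 ± 23.2 in listeria cells at 12 h (interaction 1.58, 0.00383). Of the type I list 4 of 36 moved upward and none downward (13 and none adjusted over the list alone), and of the interferon gamma list 3 of 28 and none (7 and none adjusted over the list alone). Tnfaip3, an inhibitor of NF-kB signalling, moved downward by -1.47 (0.00383) and Tnfrsf9, the costimulatory receptor 4-1BB, by -1.02 (0.0218). Tnfrsf9 was lost without listeria_6h replicate 1, listeria_12h replicate 2 or tumor_12h replicate 2 (5.05e-06 to 0.0743 over 20 alternatives). Pdcd1 gave no evidence of change between 6 and 12 h (0.91, adjusted p = 1.00). The count of 47 became 142 in the fit of 16 activated libraries, 325 by DESeq2's Wald test and 140 without tumor_24h replicate 1. It was 28 without listeria_6h replicate 1, 31 without listeria_6h replicate 3, 25, 28 and 31 without listeria_12h replicate 1, 2 or 3, and 23 without tumor_12h replicate 2.

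Between 6 and 24 h the difference changed for 609 genes, 419 upward in tumor and 190 downward. Tcf7 moved upward by 2.17 on the log2 scale (adjusted p = 0.00111), while Ifng moved downward by -3.55 (0.00147), Il2 by -2.51 (0.0192) and Myc by -1.83 (0.0159). The type I list had 15 of 36 upward and none downward (26 and 1 adjusted over the list alone), the interferon gamma list 8 of 28 and none (16 and none adjusted over the list alone), naive and memory genes 7 of 25 and none (11 and 2 adjusted over the list alone) and homing receptors 5 of 20 and none (8 and none adjusted over the list alone). Irf1, an interferon-induced transcription factor, moved upward by 3.63 (5.89e-07). The count of 609 became 273 in the fit of these groups alone and 1560 by the Wald test, and without tumor_24h replicate 2 it was 5356. It was 399 without listeria_6h replicate 3 and 363, 396 and 325 without listeria_24h replicate 1, 2 or 3.

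Within the tumor arm, the comparison of times asks how the response unfolds. Between 6 and 12 h, DNA replication genes appeared in tumor cells: Cdc6, a replication licensing factor, went from 0.0186 ± 0.0323 to 22.3 ± 11.2 CPM (log2 9.74, adjusted p = 0.00484) and Cdc45, part of the replicative helicase, from 2.30 ± 2.06 to 40.8 ± 15.1 (4.14, 0.00350). Activation genes fell at the same time, as for Nr4a1 from 2650 ± 12.3 to 574 ± 140.2 CPM (-2.21, 0.000925), Tnf from 1029 ± 29.9 to 322 ± 42.5 (-1.68, 1.13e-05), Il2 from 309.7 ± 13.9 to 60.7 ± 15.1 (-2.35, 0.00168) and Cd69 from 663 ± 178 to 105 ± 4.92 (-2.65, 0.00145). Cd8a rose from 340 ± 37.7 to 789.9 ± 149.8 CPM (1.22, 0.00157). In all 549 genes rose and 184 fell. Of the S phase list 17 of 30 rose and none fell (21 and none adjusted over the list alone), and of the early TCR list 8 of 25 fell and none rose (15 and 1 adjusted over the list alone). Among the other largest changes Dtl rose (4.76, 0.0190), lost without any 1 tumor_6h library or tumor_12h replicate 3 (3.39e-06 to 0.1 over 14 alternatives), and Ndrg1 fell (-2.78, 0.00157). The total of 733 was 375 without tumor_6h replicate 1, 456 without tumor_6h replicate 2, 460, 435 and 431 without tumor_12h replicate 1, 2 or 3, and 1681 without tumor_24h replicate 1.

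Between 12 and 24 h in tumor cells 383 genes rose and 247 fell. Mitosis genes rose in 4 of 25 members and none fell (9 and none adjusted over the list alone), with Cenpa from 15.9 ± 0.476 to 165.0 ± 4.48 CPM (n = 2, log2 3.38, adjusted p = 0.00355). S phase genes rose in 7 of 30 (13 adjusted over the list alone). Selplg, a ligand for leukocyte rolling on endothelium, rose from 71.5 ± 24.3 to 673 ± 240.3 CPM (3.23, 0.00104), Ly6c2 from 34.8 ± 24.5 to 565 ± 96.3 (4.02, 8.53e-05) and Psmb9 from 45.6 ± 9.25 to 229 ± 0.0538 (2.33, 3.73e-06). Lta fell from 929 ± 127 to 183 ± 28.1 (-2.35, 0.000132). Without tumor_24h replicate 2 the total of 630 became 6096, without tumor_12h replicate 1 it was 257 and without tumor_12h replicate 2 it was 334, and edgeR's fit of these 5 libraries alone called 0, with 1357 at an unadjusted p under 0.05, against 1898 by DESeq2's Wald test.

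In listeria cells the same question covers the course of an acute response. Between 6 and 12 h 61 genes rose and 36 fell. Mcm5, a helicase subunit of DNA replication, rose from 183 ± 58.7 to 564 ± 127 CPM (log2 1.62, adjusted p = 0.00933), and Rrad, a small GTPase, fell from 137 ± 22.0 to 41.1 ± 8.76 (-1.74, 0.00577), lost without listeria_12h replicate 2 and in the fit of the 2 groups alone (0.0689). Of the S phase list 2 of 30 rose (16 adjusted over the list alone), and of oxidative phosphorylation 3 of 26 (19 adjusted over the list alone). The total of 97 was 0 in edgeR's fit of these 6 libraries alone, with 1974 at an unadjusted p under 0.05, and 714 by DESeq2's Wald test. It was 27, 38 and 18 without listeria_6h replicate 1, 2 or 3, 63, 8 and 39 without listeria_12h replicate 1, 2 or 3, and 397 without tumor_24h replicate 1. Between 12 and 24 h 3 genes rose and 10 fell. Those that rose were Ccne1, Asf1b and Mcm7, all of DNA replication and the entry into it. Asf1b and Mcm7 were lost without any 1 of the 6 libraries (adjusted p up to 0.194 and 0.291), and Ccne1 without listeria_12h replicate 1 or 3 or any 1 listeria_24h library (up to 0.194). Tnfaip3 fell from 208 ± 4.48 to 71.4 ± 12.7 CPM (-1.55, 0.000261, 14 of 14 alternatives) and Tnf from 612 ± 85.8 to 286 ± 24.3 (-1.10, 0.00584). The total of 13 was 8 without listeria_12h replicate 1 or 2, 3, 8 and 3 without listeria_24h replicate 1, 2 or 3, 89 without tumor_24h replicate 1 and 190 by the Wald test.

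The comparisons with naive cells set both arms against a separate reference. The naive libraries differ from the activated ones in sex and title prefix, as given below, so they do not show the level from which the arms started. Within 6 h several effector and activation genes that were at 0 or low in naive cells were far higher in both arms. Ifng, at 0 in each naive library, was at least 4744-fold higher in tumor_6h and at least 12510-fold higher in listeria_6h, Ccl3 at least 96470-fold and 12410-fold, and Lad1, a basement membrane filament protein, at least 25920-fold and 10080-fold. Nr4a1 was at 14.5 ± 1.76 CPM in naive cells, 2650 ± 12.3 in tumor_6h and 2226 ± 543 in listeria_6h. Pdcd1 was at 2.92 ± 2.84 CPM in naive cells, against 760.6 ± 30.5 in tumor_6h (log2 8.02, adjusted p = 1.23e-06) and 304.0 ± 41.9 in listeria_6h (6.70, 5.02e-06). Il7r, the interleukin 7 receptor chain of resting T cells, was at 487 ± 13.7 CPM in naive cells and at 0.0186 ± 0.0323 in tumor_6h and 1.68 ± 0.8 in listeria_6h. Tcf7 was at 2018 ± 22.1 CPM in naive cells, 69.0 ± 7.37 in tumor_6h and 255 ± 89.6 in listeria_6h.

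At 6 h, 3949 genes were higher and 2603 lower in tumor than in naive cells, and 3998 and 2171 in listeria cells. The early TCR list had 19 of 25 higher in tumor_6h (adjusted p = 2.24e-20, and 0.000644 with an estimated correlation) and 23 in listeria_6h (4.24e-26, and 0.000641), 23 in each adjusted over the list alone. Ribosome biogenesis had 27 of 30 higher in tumor_6h (3.82e-25, and 0.000644) and 26 in listeria_6h (2.03e-23, and 0.000644), 28 and 26 adjusted over the list alone. Of the naive and memory list 19 of 25 were lower in tumor_6h (9.89e-12, and 0.0743 with an estimated correlation) and 17 in listeria_6h (7.33e-08, and 0.149), 19 and 21 adjusted over the list alone. Among the largest lower changes in tumor_6h, S1pr1, the receptor for exit from lymphoid tissue, was at least 7134-fold lower, Slc28a2b at least 4546-fold, Ifi206 at least 2809-fold and Adgrg5 at least 2340-fold. In listeria_6h Card6 was at least 503.5-fold, Mturn at least 392.1-fold and Zbtb38 at least 303.6-fold lower. Tox was lower than in naive cells, at 21.4 ± 8.63 CPM in tumor_6h and 8.81 ± 2.81 in listeria_6h against 64.7 ± 8.11; the tumor call (adjusted p = 0.0151) was lost without tumor_6h replicate 3 (0.0666) and passed in the other 12 of 13 alternatives.

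The interferon lists set the arms apart against naive cells too. In tumor_6h 33 of 36 type I genes were lower than in naive cells and none higher, with a median of -5.44, or -5.02 at the bounds (34 lower adjusted over the list alone; adjusted p = 1.42e-16, and 0.0164 with an estimated correlation), whereas in listeria_6h 19 were higher and 2 lower, with a median of 2.31 (19 and 2 adjusted over the list alone; 0.00156, and 0.346 with an estimated correlation). In tumor cells 28 were lower and 1 higher at 12 h (5.8e-13, and 0.0164 with an estimated correlation), and 20 and 2 at 24 h (4.62e-06, and 0.149 with an estimated correlation). The interferon gamma list had 22 of 28 lower in tumor_6h and none higher (2.41e-14, and 0.00168 with an estimated correlation), and 2 lower and 5 higher in listeria_6h (0.537). By 24 h S phase genes were higher than in naive cells in both arms, 24 of 30 in tumor (median 3.06, 1.08e-10, and 0.0863 with an estimated correlation) and 23 in listeria cells (median 2.63, 1.04e-05, and 0.220 with an estimated correlation).

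At 12 h, 4137 genes were higher and 2009 lower than in naive cells in tumor and 4087 and 2193 in listeria cells, and at 24 h 3806 and 2065 in tumor and 4331 and 2285 in listeria cells. In the fit of the compared groups alone the tumor_24h counts were far smaller, as given with the alternatives below. Tumor and listeria cells shared 3401 higher and 1679 lower genes at 6 h, 3622 and 1583 at 12 h and 3362 and 1392 at 24 h. Independent lists would share 944 and 338, 1011 and 263, and 986 and 282. Unchanged groups simulated against the same naive libraries shared 0, but with no gene changed hardly any could be called. This 0 therefore does not measure what shared controls add to the overlap. The covariance of the log2 fold changes was 9.20 at 6 and 12 h and 9.43 at 24 h, against 0.20, 0.20 and 0.28 in the simulations. The simulated groups were drawn around the mean of the same naive libraries, so that covariance does not size what shared controls add either. The 3 naive libraries were not split between the arms, so part of the excess may come from the shared controls.

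Every naive comparison depends on the scaling. With DESeq2's size factors the median log2 fold change of all genes moved to between -0.725 and -0.423, and the share of higher calls fell from 60.3% to 67.3% with TMM to 45.5% to 49.3%, for example to 2984 higher and 3576 lower in tumor_6h and 2989 and 3281 in listeria_6h. Without tumor_24h replicate 1 the genes lower than in naive cells numbered 3982 and 3448 in tumor cells at 6 and 12 h and 3651, 3747 and 3818 in listeria cells at 6, 12 and 24 h. Those lower in tumor_24h numbered 5366 without replicate 2, and those lower in listeria_24h 1518 and 1490 without listeria_24h replicate 1 or 3. Naive libraries also had 0.318% to 0.375% of counts from mitochondrial genes, against 0.050% to 0.127% in activated libraries, and carry another title prefix in the labels. Sex differs as well: naive libraries held Xist, which only female cells express, at 12.7 to 35.6 CPM and almost no counts of Ddx3y, Eif2s3y, Kdm5d and Uty on Y. Activated libraries had no Xist and a sum of 14.3 to 55.8 CPM over these Y genes, except tumor_24h replicate 1 at 0. Sex, preparation and activation therefore cannot be separated in any comparison with naive cells.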

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

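For the patterns weighed below, the tests of sequencing depth, of the time in tumor, of all 3 explanations of the interferon difference and of separate preparation were chosen after the result was seen, while those of few molecules, sex, deeper sequencing and other splits were written before.

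The tumor and listeria difference changed with time by an interaction test, which sets these results apart. Between 6 and 12 h it changed for 47 genes. By the naming rule the largest upward values were in Oasl1 (log2 11.05), Ifit3b (9.51) and Ifi206 (8.63) and the largest downward values in Tnfrsf9 (-1.02), Tmem131l (-1.06) and Tnfaip3 (-1.47). Of these, Ifit3b was lost without listeria_6h or tumor_6h replicate 1 or 3, any 1 listeria_12h library or tumor_12h replicate 2 (adjusted p up to 0.0743). Tnfrsf9 was lost without listeria_6h replicate 1 or replicate 2 of listeria_12h or tumor_12h (up to 0.0743). Tmem131l was lost in 12 of 20 alternatives, among them each without 1 library but listeria_6h replicate 3, tumor_12h replicate 1 and tumor_24h replicate 1 (up to 0.119, without the filter on low counts). Between 6 and 24 h it changed for 609 genes. By the naming rule the largest upward values were in Adgrg5 (14.73), Timp1 (13.62) and Ifit1bl1 (13.19) and the largest downward values in Csrnp2 (-5.22), Fgfrl1 (-5.95) and Kif22 (-7.19). Adgrg5 passed in all 18 alternatives. Timp1 passed in 5, lost without any 1 library of listeria_6h, listeria_24h or tumor_6h (up to 0.106) and without tumor_24h replicate 1 (log2 2.63, adjusted p = 1.00). Ifit1bl1 passed in 16, lost without tumor_24h replicate 2 (log2 3.435, adjusted p = 1.00) and in the fit of the compared groups alone (0.105). Csrnp2 passed in 6, lost without any 1 library of listeria_6h, listeria_24h or tumor_6h (up to 0.115). Fgfrl1 passed in 9, lost without replicate 2 or 3 of listeria_6h or tumor_6h or any 1 listeria_24h library (up to 0.0828). Kif22 passed in 17, lost in the fit of the compared groups alone (0.0618). Without tumor_24h replicate 2 the log2 values of Csrnp2 and Fgfrl1 were -12.75 and -12.02. Of the panel genes, Myc changed by -1.83, Ifng by -3.55, Il2 by -2.51 and Tcf7 by 2.17. Fitted values of genes at 0 in each library of a group, as Kif22 is in listeria_6h and several others are in tumor_6h, depend on the prior count. The test for a single library far from its group needs groups of 4 or more and was not applied to these groups of 2 or 3.

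Other assignments of the tumor and listeria libraries within each time were tried for the change between 6 and 12 h. Of 100 assignments, 2 gave as many genes as the 47 of the labelled one, that one included, a share under 0.05. The highest other count was 92. Assignments that kept the labelled arms at 6 h and mixed those at 12 h gave 11, 37, 10, 13, 39 and 92. The highest count with the arms at 6 h mixed was 22. Mixing the arms at 6 h removes the difference itself, so the share cannot decide whether that difference changed with time.

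Tumor_24h replicate 1 had the fewest genes with a count of the 20 libraries. Lower sequencing depth is argued against by its total of 36.2 M counts, inside the range of the others. If few RNA molecules entered the library, genes that are plainly expressed elsewhere should be missing, and 11.19% of genes at 10 CPM or more in every other activated library were at 0 in it, against 0% in each of the others when tested the same way on the remaining 15. The time spent in the tumor is argued against by the 17142 genes with a count in tumor_24h replicate 2. Few molecules would give that share, but so might a loss at any later step, and the cause is open.

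Interferon lists were lower in tumor than in listeria cells at each time. Scaling is argued against by the type I median at 6 h with DESeq2's size factors, -7.23. RNA from macrophages, neutrophils or B cells as the whole source in the listeria libraries is argued against by the type I sum. It varied by 1.09 times over the listeria_6h libraries, while the marker sums varied by 1.53, 1.65 and 2.67 times. A partial share from these cells is not excluded, since RNA of the T cells themselves would even out the sum. A rise in listeria cells alone is argued against by a type I median of -5.44 in tumor_6h against naive cells, so the tumor cells lay below the naive libraries, which also differ in sex and title prefix. Dendritic cell RNA and the tissue itself, liver or spleen, were not tested and stay open. The dendritic cell list summed to 2609, 2605 and 2385 CPM in the listeria_6h libraries, but also to 1813, 1996 and 1657 CPM in the naive ones. Of its 15 measured genes, 4 were at 10 CPM or more in every naive library. T cells may hold much of that sum, so its small variation cannot decide on dendritic cell RNA.

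Over 5000 genes were called in each comparison with naive cells. Naive libraries held Xist at 12.7 to 35.6 CPM and almost no Y counts, and activated libraries no Xist and, except tumor_24h replicate 1, 14.3 to 55.8 CPM over 4 Y genes. The share of calls on X or Y, 3.36% against 3.21% of the genes tested, with 6 of 8 Y genes called, leaves sex open, since sex can also change genes on other chromosomes, and sex cannot be told apart from activation. Deeper sequencing of naive libraries is argued against by 93.7% of calls kept after thinning every library to the lowest total. Separate preparation could not be told from activation, since 0 groups hold libraries of both title prefixes.

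Other splits of the 6 libraries were tried for each comparison of 3 with 3. In each, 1 of 10 splits, the labelled one, gave as many genes, and 10 splits are too few for a share under 0.05. The highest other count was 5 for tumor_6h against listeria_6h, where the labelled one gave 580, 0 for tumor_12h against listeria_12h (286), 0, 1, 2, 0 and 0 for tumor_6h, tumor_12h, listeria_6h, listeria_12h and listeria_24h against naive cells (6552, 6146, 6169, 6280 and 6616), and 0 for each pair of successive times (733, 97 and 13). By camera the labelled split gave 18 and 23 lists at 6 and 12 h and the highest other split 14 and 15, so list calls under the preset correlation arise readily under other groupings. Each other split holds the arms unevenly, so part of the labelled difference remains in it. These counts therefore do not show how many lists would be called without a difference.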

How the results depend on the processing

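The alternatives without tumor_24h replicate 1 and with 16 activated libraries were chosen after seeing the data, and the others before. Counts of calls kept within 1.5 times their value in 209 of 324 alternatives and moved further in 115. List results kept direction and side of the threshold in 1018 of 1147, were weaker in 106, stronger in 21 and reversed in 2, and named genes did so in 5135 of 5905, with 718 weaker, 51 stronger and 1 reversed. Removing marker, mitochondrial and immunoglobulin genes moved no count and no named gene. The cause was not tested unless stated.

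DESeq2's Wald test gave 419 genes higher and 938 lower in tumor than in listeria cells at 6 h, 316 and 420 at 12 h and 785 and 944 at 24 h. It gave 4435, 4073 and 4871 lower than naive in tumor and 4292, 4527 and 4543 in listeria cells at 6, 12 and 24 h, 1738 and 1898 changed between successive times in tumor, 714 and 190 in listeria cells, and 325 and 1560 interactions. DESeq2's size factors, which shift all genes against naive cells, gave 3159 and 3302 lower in tumor at 12 and 24 h and 3281, 3562 and 3584 in listeria cells. No filter gave 193 higher in tumor at 24 h and 393 changed between tumor_12h and tumor_24h.

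The fit of the compared groups alone gave 222 higher in tumor at 6 h, 285 higher and 360 lower at 12 h, and 0 and 0 at 24 h. Against naive cells it gave 4184 lower in tumor_12h, 424 higher and 163 lower in tumor_24h, and 3550, 3740 and 4664 lower in listeria cells. It gave 1673 and 0 changed between successive times in tumor, 0 and 38 in listeria cells, and 85 and 273 interactions. With 16 activated libraries the counts were 417 and 882 at 6 h, 273 and 460 at 12 h, 1962 between tumor_6h and tumor_12h, 606 and 130 in listeria cells, and 142 and 969 interactions.

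Replicate numbers did not pair the arms: same-numbered libraries correlated at -0.11 to 0.16 at 6 h, -0.87 to -0.25 at 12 h and 0.13 to 0.28 at 24 h over 2000 genes, best with their own number in 1, 0 and 1 of the pairs. With the replicate block 48 genes changed between listeria_6h and listeria_12h and 8 between listeria_12h and listeria_24h, and the other counts stayed within 1.5 times. Of the genes named here it ended the calls of Egr2, Ifng and Fhl2 at 6 h, Slc9b2 and Mcm7 at 12 h, and Ccl1, Bdh2 and Mcm7 at 24 h. It ended those of Ccne1, Asf1b and Mcm7 between listeria_12h and listeria_24h, of Tnfrsf9 and Tmem131l in the interaction of 6 and 12 h, and of Timp1, Csrnp2 and Fgfrl1 in that of 6 and 24 h. It also ended the list calls of effector cytokines and negative regulators at 12 h, and of inhibitory receptors, effector cytokines and naive and memory genes at 24 h.

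Leaving out 1 library gave 61 to 316 higher and 320 to 818 lower in tumor at 6 h, 48 to 232 and 129 to 383 at 12 h, and 142 to 899 and 170 to 4880 at 24 h. Against naive cells it gave 1946 to 3982, 1364 to 3448 and 1778 to 5366 lower in tumor and 1565 to 3651, 1506 to 3747 and 1490 to 3818 lower in listeria cells at 6, 12 and 24 h. Changes with time numbered 375 to 1681 and 257 to 6096 in tumor and 8 to 397 and 3 to 89 in listeria cells, and interactions 23 to 140 and 325 to 5356. Where tumor_24h keeps 1 library, that library is assumed to vary like the other groups. Without tumor_24h replicate 2, Ctla4 in tumor_24h against naive cells reversed to a log2 of -10.808 (up to 1.050 without other libraries). Against listeria cells at 24 h the naive and memory list reversed there to a median of -1.271 (up to 0.541 without other libraries). The direction of the camera test of the dendritic cell list turned, at a median of -2.655 (-2.884 to -1.664 without other libraries).

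The interferon lists passed in all 11 alternatives at 6 and 12 h and all 9 at 24 h. Thinning every library to the lowest total kept 93.7% of calls in tumor_6h against naive cells.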

Other observations

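Ighm, the immunoglobulin heavy chain constant gene, was among the higher transcripts of tumor_24h. It stood at 763 ± 65.1 CPM in tumor_24h (n = 2) and 164 ± 23.1 in listeria_24h (n = 3), a log2 fold change of 2.22 (adjusted p = 7.62e-05 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and rose in tumor cells from 275 ± 18.8 CPM at 12 h (log2 1.48, adjusted p = 0.0025). The fit of the compared groups alone ended both calls. In naive libraries, with Ighm at 1496 to 1853 CPM before TMM scaling, the summed counts of other B cell genes came to at most 2.02% of those of Ighm. That share was 36.28% and 5.59% in tumor_24h replicates 1 and 2 and 88.58% to 240.59% in the listeria_24h libraries. If B cell RNA made the difference with listeria_24h, that share would be at least as high in tumor_24h. It was lower in both tumor libraries, which argues against B cell RNA as the main source of that difference. A smaller part from B cells is not excluded, and the rise from 12 h was not weighed.

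Tumor_12h replicate 2 held 2919 CPM over the neutrophil and monocyte list, 28.6 times the mean of the other tumor_12h libraries (3.74 times for the macrophage list), with S100a8 at 333, S100a9 at 538 and Lyz2 at 723 CPM. In tumor_24h replicate 1 the sum was 4713 CPM, with S100a8 at 813, S100a9 at 928 and Lyz2 at 874 CPM. Trav9-2 took 70.1% to 88.0% of the counts of Trav genes in all libraries.

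Replicate libraries of a group correlated at 0.964 to 0.991 in log2 CPM, except for the tumor_24h pair at 0.819. No pair was a duplicate: the chi-square per gene between replicates was 17.6 to 162.6, and 589.8 for the tumor_24h pair.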
